A study of Rattus norvegicus with 16 samples.

How the data were processed

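Methylation was measured in the amygdala of female Long-Evans offspring, in 16 libraries made with the Ovation RRBS Methyl-Seq kit per the labels' protocols. Each deposited file lists CpG cytosines of 1 library by chromosome, position and strand, with methylated and unmethylated read counts as deposited by the authors, without normalization. The genome build was Rnor_6.0 per the submitters' processing notes. The names of the deposited files carry words for trimming and for Bismark with Bowtie 2; the program that wrote the tables and its version are not given in the sources used here. A further column in the files was not used. In all 16 files every listed site had at least 1 methylated read, so a site without methylated reads cannot be told from a site that was not read, and shared sites were shared among sites with a methylated read. Positions were used as the files give them; 31.9% of minus-strand sites had a plus-strand partner 1 bp before them and 1.98% 1 bp after.

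The labels gave diet and age. The library set came from the titles, and names of the files differed between the sets too, so processing by the authors may have differed between them. The diet comparison at P7 used set A only. At P90 and in controls over age, library set was a covariate in the logistic fits, but not in the tests of mean methylation. The high-fat libraries of P7 and P90 belong to different sets, so their change with age was not tested.

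Sites entered a comparison if read at least 10 times in each of its libraries and not above the 99.9th percentile of coverage of any of them. The reads of at least 3 such sites were summed in windows of 1 kb (1000 bp). No annotation of the build was used here, so windows of the whole genome took the place of promoters, gene bodies and intergenic regions, and no gene is named. This replacement was fixed before the data were examined. Gene list tests and the alternative promoter definition were therefore not run.

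A logistic model of methylated and unmethylated counts was fitted per window or site. The deviance was tested by an F test, two-sided, with the Pearson dispersion moderated over features by empirical Bayes with a trend in coverage and level where at least 500 features were tested, and never below 1. Features with an outlying dispersion kept their own value. That step was added after the counts without it had been seen, and the count without it is given in the closing section. For CpG sites at P7 the moderation gave nearly all weight to the trend, and 1345 of 600479 sites kept their own dispersion. The p-values of the other sites therefore do not measure the spread of each site between libraries. At chromosome 18, 71851035 the dispersion was 1.28, though the control P7 libraries had an SD of 28.8 points. P-values were adjusted by Benjamini-Hochberg at 0.05. Mean methylation over sites, taken without the upper limit on coverage, was compared by exact permutation tests, two-sided, of which the smallest p is 0.0286 for 4 against 4 libraries and 0.0667 for 2 against 4. Windows and sites named in the text were the 2 with the smallest p in each direction that passed, and the 5 with the smallest p for the interaction. For age, the fixed fit called none; the 5 in each direction of set A alone were named, a number chosen after the data were seen.

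Alternatives tried were a minimum of 20 reads, no upper limit on coverage, at least 5 sites per window, edgeR 4.0.16 on counts with a term per library, limma 3.58.1 on log2 of the ratio of counts plus 1, Fisher's exact test on pooled counts, a difference of at least 10 points, no set term, single sets, merged strands, thinning to 10 reads, a replicate block and leaving out each library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.

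The test was checked on simulated counts drawn with the real coverage and level, and with 1 spread per library set shared by all features. In 1 run without any change at P7 it called 0 windows and 0 sites. Other groupings of the real P7 libraries gave a median of 1 window and 75 sites. Differences in spread between features were not simulated, so the shares below may look better than in the real data. With 200 of 88651 windows changed in the P7 comparison, the test recovered 34.3% of changes of 10 points, 91.0% of 20 points and 100% of 30 points, and 9.09% of its calls were false. For 600479 sites it recovered 0%, 17.9% and 59.1%. For age in set A alone (93730 windows) it recovered 23.9%, 82.1% and 95.5%. The spread of set B was so large that the P90 and interaction fits recovered at most 7.5% of changes of 30 points in windows. With set B given the spread of set A, the P90 fit recovered 100% of them in 77 windows, and the age fit of all controls recovered 100% in 5701 windows. The interaction fit then recovered 12%, 37.5% and 70% of changes of 10, 20 and 30 points in 65 windows, so it stayed weaker without that spread. Read counts without molecular identifiers are not independent molecules, so errors from read counts cover counting only.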

Results

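The amygdala of female Long-Evans rat offspring was profiled by reduced representation bisulfite sequencing, which reads cytosine methylation mainly in CpG-rich fragments of the genome. The dams had been fed a high-fat or a control diet before pregnancy, through gestation and through lactation. The offspring were taken at postnatal day 7 (P7) or at postnatal day 90 (P90), the latter after weaning to control diet, and did not eat the high-fat diet themselves. Each of the 4 groups held 4 libraries, 16 in all. The labels do not say whether libraries came from separate litters, so p-values refer to these libraries and not to litters. For windows they measure a spread between libraries that combines each window's own with one shared over windows. At P7 the shared part counted as 22.3 degrees of freedom and the own part as 6. For age in set A alone (library sets are described below) these were 27.4 and 4, so both sets of p-values rest mostly on the shared spread. For P90 windows the own part counted more (1.22 shared and 5 own). For CpG sites at P7 the p-values measure mostly a spread shared over sites.

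The libraries fell into 2 sets by the style of their titles. Set A held all 8 P7 libraries and control P90 replicates 1 and 2. Set B held control P90 replicates 3 and 4 and the 4 high-fat P90 libraries. Titles or file names give lane 5 for control P90 replicate 3 and lane 6 for the other set B libraries. Lane was not a term in any fit. The 10 libraries of set A listed 1796735 to 2188584 CpG cytosines with 22087054 to 63677193 reads per library. The 6 libraries of set B listed 214222 to 752866 with 7802161 to 21333037 reads. At sites read at least 10 times, mean methylation was 62.6% to 68.5% in set A and 87.3% to 91.8% in set B. Within a group, methylation at shared sites correlated at r of 0.928 to 0.950 across sites between set A libraries and at 0.352 to 0.485 between set B libraries, where sites are not independent replicates. The lowest mean chi-square per site between libraries of 1 group was 1.185, where reads drawn again from the same library would give about 1.

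**Figure D1:**
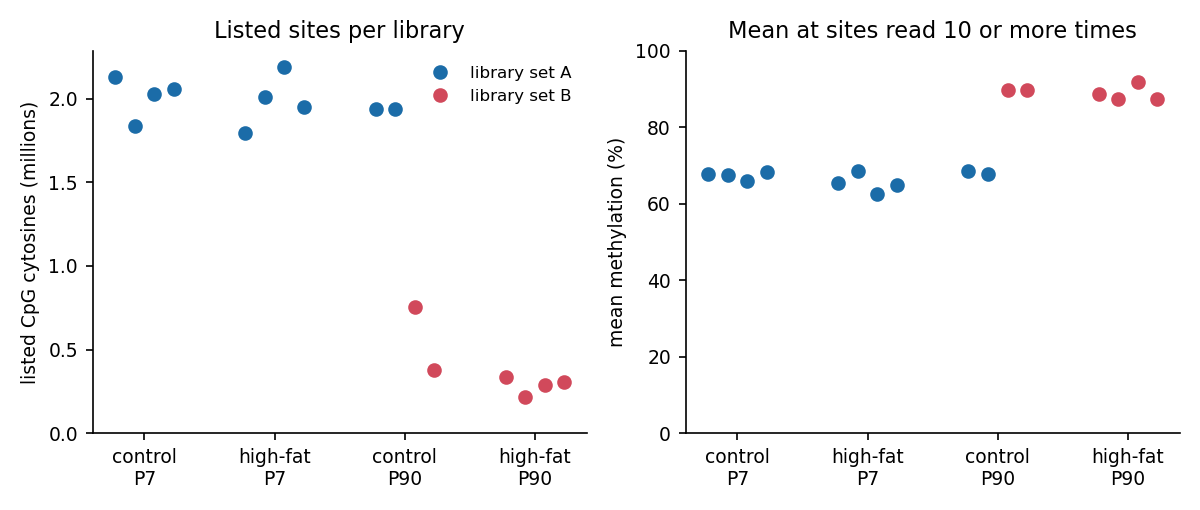
Number of CpG cytosines listed per library (left) and mean methylation in percent at sites read at least 10 times (right), 1 point per library, by group and library set. The 6 set B libraries lie at 214222 to 752866 sites and 87.3% to 91.8%, apart from the 10 set A libraries.

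The change between early life and adulthood was compared in control-diet offspring. In set A, most windows called higher at P90 had a mean methylation under 60%, while among windows above 60% more were called lower than higher. Of 93730 windows of 1 kb, 6801 were higher and 4458 lower at P90 in the 2 P90 libraries against the 4 P7 libraries (moderated logistic model, adjusted p under 0.05). Windows called higher went from a median of 40.1% at P7 to 60.5% at P90, and windows called lower from 83.7% to 68.9%. Among windows with a mean of 0 to 20%, 28.5% were called higher and 1.55% lower. Among windows with a mean of 80 to 100%, 1.74% were called higher and 3.56% lower, and the median change of all windows there was 0.208 points. Mean methylation over all windows was 75.6% ± 0.849 (SD, n = 4) at P7 and 76.5% ± 0.0780 (SD, n = 2) at P90 (two-sided exact permutation p = 0.400, where 0.0667 is the smallest this design allows).

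The windows of this comparison with the smallest p differed by 29.7 to 44.2 points where higher. On chromosome 16, 69096001 to 69097000 (Rnor_6.0; 34 sites, 985 to 1621 reads per library), methylation was 12.5% ± 1.33 (SD, n = 4) at P7 and 42.2% ± 0.984 (SD, n = 2) at P90 (adjusted p = 1.11e-09). On chromosome 1, 218378001 to 218379000, it was 27.5% ± 0.531 and 65.8% ± 5.77. On chromosome 7, 143710001 to 143711000, it was 27.3% ± 1.60 and 62.4% ± 2.94. On chromosome 6, 11297001 to 11298000, it was 45.2% ± 3.68 and 83.4% ± 4.16. On chromosome 2, 236085001 to 236086000, it was 18.8% ± 2.59 and 63.0% ± 11.2. Among windows that were lower, chromosome 10, 86687001 to 86688000 (13 sites, 169 to 467 reads) went from 81.6% ± 4.91 to 36.2% ± 6.05 (adjusted p = 1.53e-09). Chromosome 1, 240911001 to 240912000 went from 70.8% ± 4.93 to 19.9% ± 4.02, and chromosome 1, 78747001 to 78748000 from 83.6% ± 1.68 to 45.2% ± 1.95. Chromosome 10, 15277001 to 15278000 went from 85.5% ± 2.99 to 55.2% ± 2.09, and chromosome 14, 114540001 to 114541000 from 81.7% ± 5.42 to 32.4% ± 2.41. What genes lie at these positions was not analysed here.

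**Figure D2:**
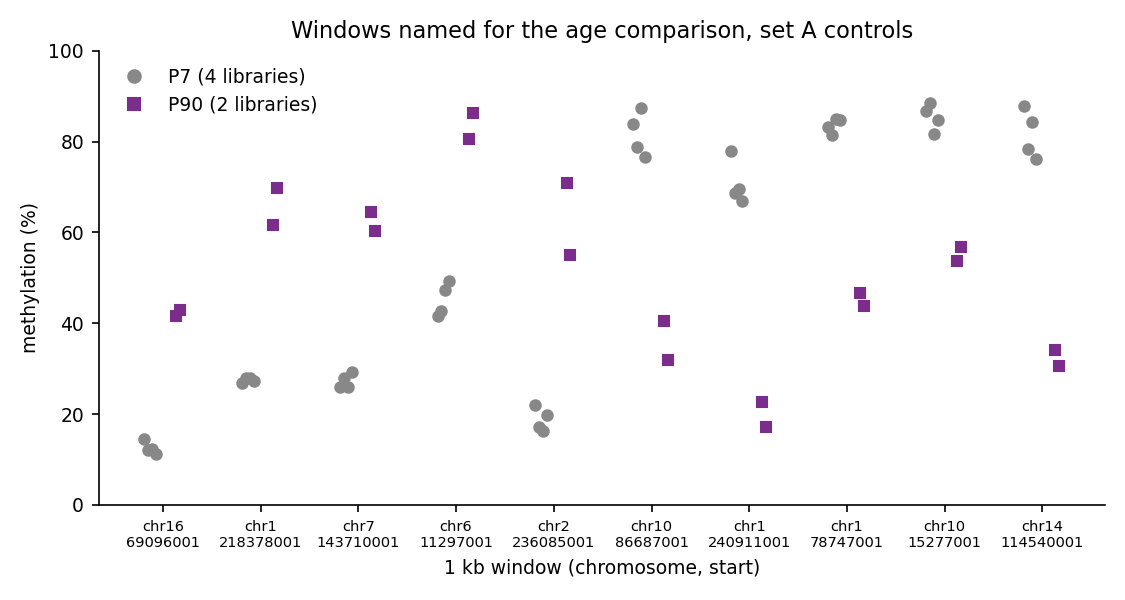
Methylation in percent of the 10 windows named for age, 1 point per set A control library, with 4 P7 libraries as circles and 2 P90 libraries as squares. In each window the P90 libraries lie outside the range of the P7 libraries, as at chromosome 16, 69096001 (12.5% and 42.2%).

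Adjacent windows that were both called mostly had the same direction. Of 514 pairs of adjacent windows that were both called, 475 (92.4%) had the same direction, where 52.2% is given by the shares of the directions alone. Next to a called window 28.6% of windows were called, against 12.01% of all windows, so most neighbours of called windows were not called. The longest run was 5 windows on chromosome 19, 25897001 to 25902000, which held 13.6% ± 0.748 (SD, n = 4) at P7 and 27.7% and 23.9% in the P90 libraries. Of 1392 windows on the X chromosome, 41 (2.95%) were higher and 5 (0.359%) lower. On the autosomes these shares were 7.32% and 4.83%, so X windows were called less often in both directions.

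**Figure D3:**
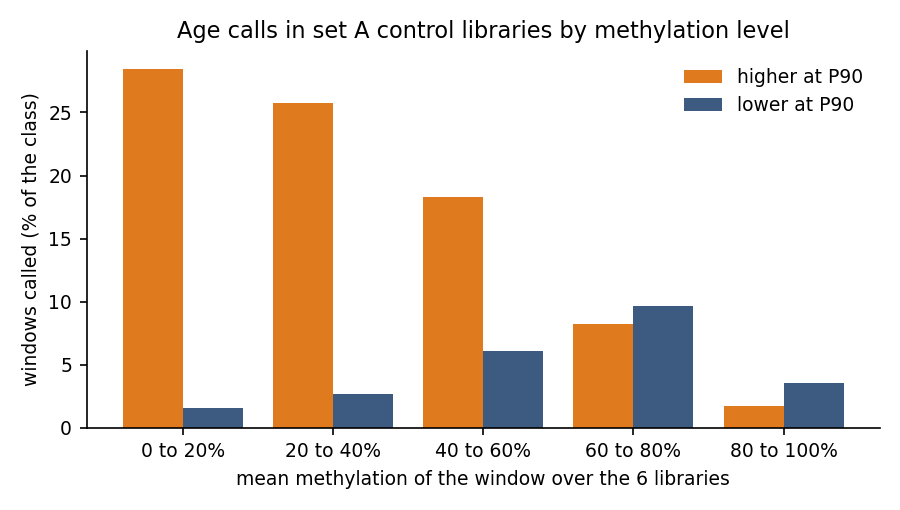
Share of 1 kb windows in percent called higher (orange) or lower (blue) at P90 in set A control libraries, by the mean methylation of the window over the 6 libraries. The share called higher falls from 28.5% at 0 to 20% to 1.74% at 80 to 100%.

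The comparison fixed before the data were examined used all 8 control libraries with a term for library set, and it called 0 of 5701 windows, with 435 at an unadjusted p under 0.05. edgeR and limma also called 0 on these windows. Without control P90 replicate 3 it called 425, and without control P90 replicate 4 it called 424, where the 1 set B library left is absorbed by the set term and adds no spread. In simulations with the measured spread of set B this fit recovered 0% of changes of 30 points, against 95.5% in set A alone. Leaving out 1 of the P90 libraries in set A alone gave 6416 windows (without replicate 1) and 6179 (without replicate 2).

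The diet of the dam was compared at P7 with 4 libraries on each side. Few positions were called. Of 88651 windows, 1 was called higher and 2 lower in high-fat offspring, and of 600479 CpG sites, 47 higher and 62 lower. In simulations with 1 spread shared by all features, this test recovered 34.3% of window changes of 10 points and 91.0% of 20 points. In sites it recovered 0% of changes of 10 points, 17.9% of 20 points and 59.1% of 30 points. The small number of calls therefore does not show that site differences, or window differences of 10 points, were few. Mean methylation over 601781 sites was 74.7% ± 1.23 (SD, n = 4) in high-fat and 75.02% ± 0.856 (SD, n = 4) in control offspring (two-sided exact permutation p = 0.629).

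The window with the smallest p lay on chromosome 2, 134765001 to 134766000 (9 sites, 195 to 662 reads per library), with 85.4% ± 1.08 (SD, n = 4) in high-fat and 96.6% ± 0.488 (SD, n = 4) in control offspring (adjusted p = 0.000112). A CpG in it, read on both strands, gave the sites with the smallest p among those lower. At position 134765978 on the plus strand, methylation was 41.4% ± 11.5 in high-fat and 97.6% ± 2.16 in control offspring (19 to 75 reads). At position 134765979 on the minus strand it was 52.3% ± 5.58 and 95.4% ± 1.87. High-fat minus control was -56.1 and -43.2 points on these strands, and -11.2 points over the 9 sites of the window. The window contains this CpG, so its call came mainly from it. The window is not a separate result and does not show a change over its whole length. Chromosome 5, 58283001 to 58284000 (3 sites) held 61.7% ± 1.36 in high-fat and 91.7% ± 8.62 in control offspring (adjusted p = 0.00462). Chromosome 4, 18172001 to 18173000 (5 sites) held 95.8% ± 1.24 and 84.9% ± 2.25 (adjusted p = 0.0474). Among sites that were higher, chromosome 13, 101252036 on the plus strand held 85.0% ± 6.80 and 37.2% ± 5.02, and chromosome 18, 71851035 on the minus strand held 99.0% ± 1.33 and 52.8% ± 28.8. In each of these windows and sites all 4 libraries of one diet lay outside the range of the other. The chromosome 4 window did not pass without any of the libraries other than high-fat replicate 3 (adjusted p of 0.0564 to 0.170). limma called 0 windows and 12 sites, and edgeR 2 windows and 222 sites. Merging strands gave 239 sites, and leaving out a step of the test that was added after its effect was seen gave 361. The 3 windows became 15, 12 and 6 without high-fat replicates 1, 2 and 3, and 7, 7 and 5 without control replicates 1, 2 and 3. The sites became 197 without high-fat replicate 1. Of the 35 ways to split the 8 libraries, the real one included, 12 gave as many windows and 6 as many sites. Some other groupings thus gave counts as large, though the median of the others was 1 window and 75 sites.

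**Figure D4:**
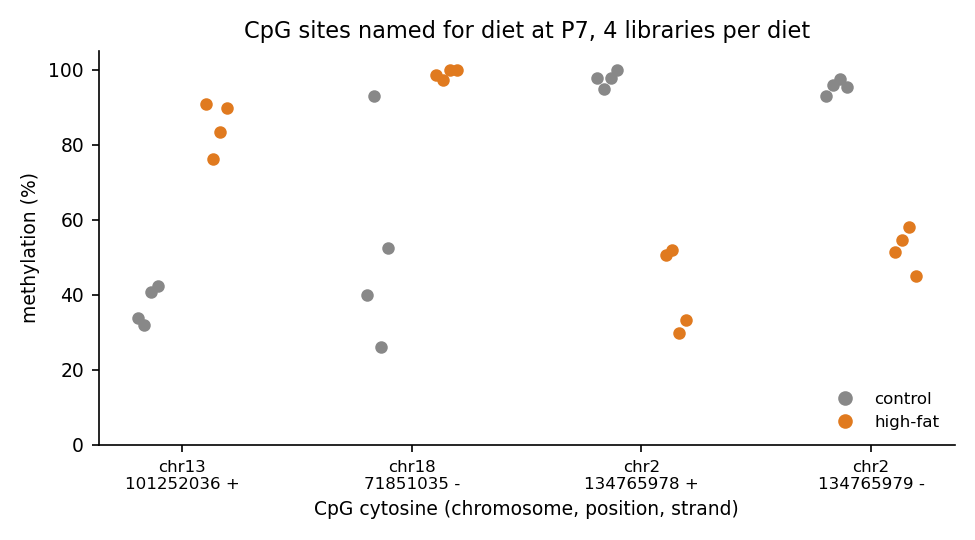
Methylation in percent at the 4 CpG cytosines named for diet at P7, 1 point per library, with control in grey and high-fat in orange. At chromosome 2, 134765978 the high-fat libraries average 41.4% and the controls 97.6%.

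At P90 the diet comparison asked whether a difference was present in adulthood, and it rested on 2 control against 4 high-fat libraries of set B. Of the 914 sites read at least 10 times in all 8 libraries, 657 lay under the upper limit on coverage and were tested, and 77 windows held at least 3 of them. The window on chromosome 5, 24430001 to 24431000 (4 sites, 83 to 772 reads) was the 1 window called, with 99.94% ± 0.130 (SD, n = 4) in high-fat offspring and 86.3% ± 2.36 (SD, n = 2) in set B controls (adjusted p = 0.00212). The set A controls had 97.6% ± 0.476 (SD, n = 2) there. This window passed without each of the 8 libraries in turn (adjusted p of 0.00404 to 0.0226), and did not pass in edgeR (0.0716) or with reads thinned (0.0527). Of the sites, 10 were higher and 0 lower. Within set B, high-fat libraries listed 214222 to 337823 sites and controls 752866 and 375819. At sites with a set A mean of 40 to 60%, high-fat libraries had 72.0% to 79.1% of values at or above 95%. The set B controls had 55.9% and 69.6%. Such a difference between libraries could also raise high-fat values, and cannot be told apart from diet here. Chromosome 13, 52783372 on the minus strand held 100% in each high-fat library and 80.5% and 100% in the set B controls (adjusted p = 0.0340). Chromosome 18, 56169897 on the plus strand held 99.87% ± 0.266 (SD, n = 4) against 100% and 49.6%. The call on chromosome 13 ended without any library other than control replicate 4 (adjusted p of 0.0896 to 1), and that on chromosome 18 without any other than control replicate 3 (0.108 to 1). Windows called became 4 and 7 without control replicates 3 and 4, and 2 and 3 without high-fat replicates 1 and 4. Sites called became 38 and 44 without control replicates 3 and 4, and 0 without any other library. Without control replicate 3 or 4 a single set B control is left, so the spread comes from the other libraries alone. Within set B alone, 1 of 100 windows and 0 of 906 sites were called, with edgeR at 0 windows and 0 sites in all 8 libraries. In simulations without any diet difference this fit made a call in 10 of 20 runs over windows and in 5 of 20 over sites (0.9 sites per run on average). Of differences of 30 points it recovered 7% in windows and 0% in sites, so the small number of calls does not show that diet differences were few. Mean methylation over 914 sites was 77.8% ± 0.587 (SD, n = 4) in high-fat and 76.2% ± 1.84 (SD, n = 4) in control offspring (two-sided exact permutation p = 0.171). This test exchanged libraries between the sets. Control libraries held 74.3% and 75.2% in set A and 76.6% and 78.5% in set B, so the difference is partly one of set. Within set B, mean methylation was 73.3% ± 0.784 (SD, n = 4) and 72.3% ± 1.45 (SD, n = 2) over 1163 sites (exact permutation p = 0.400).

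Whether the diet difference changed with age was tested over all 16 libraries, in 65 windows. The 4 windows called had a larger high-fat minus control difference at P90 than at P7, and none of the 4 passed in edgeR (adjusted p of 0.101 to 0.273), whose 1 call had the opposite direction. The difference of differences was 2.21 points on chromosome 13, 52783001 to 52784000 (adjusted p = 0.0139), 12.8 on chromosome X, 64122001 to 64123000 (adjusted p = 0.0466), 11.1 on chromosome 5, 24430001 to 24431000 (adjusted p = 0.0466) and 10.2 on chromosome 2, 196337001 to 196338000 (adjusted p = 0.0466). Chromosome 20, 12793001 to 12794000 was next, at 2.19 points, and did not pass (adjusted p = 0.0550). Set B controls held 95.8% and 100% in the chromosome 13 window, 100% and 75.6% in the X window and 100% and 82.5% in the chromosome 2 window. High-fat P90 means there were 99.97%, 99.88% and 99.69%, so each of these differences came mainly from a single set B control. The chromosome 13 window did not pass without control P90 replicate 3 (adjusted p = 0.918). The chromosome 5 window did not pass without any control P7 library, high-fat P7 replicate 1 or 4, control P90 replicate 1 or 2 or high-fat P90 replicate 3 (0.0502 to 0.236). The chromosome X window passed only without high-fat P7 replicate 3, control P90 replicate 3 or high-fat P90 replicate 1 or 4 (0.0502 to 0.784 otherwise). The chromosome 2 window passed only without control P90 replicate 3 or high-fat P90 replicate 4 (0.0549 to 0.637 otherwise). The chromosome 20 window passed without high-fat P7 replicate 3 (0.0467), high-fat P90 replicate 4 (0.0457) or control P90 replicate 4 (0.00494). In simulations with no interaction this fit made a call in 13 of 20 runs. At P90 it called 12 windows without high-fat replicate 4, 9 without control replicate 4 (with a single set B control left), and 1 without control replicate 1, control replicate 2 or high-fat replicate 3. At P7 it called 1 without control replicate 1, 2 or 4 or high-fat replicate 1 or 4, and 2 without control replicate 3 or high-fat replicate 2.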

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

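The tests of the set B pattern, of unconverted cytosines on mitochondrial DNA and as the whole cause, and the counts over other splits were chosen only after the result each bears on was seen.

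The 6 set B libraries stood apart, which bears on the P90 diet values. At sites where set A averages 40 to 60%, 55.9% to 79.1% of the values of a set B library lay at or above 95%. With values at or below 5% counted too, the shares were 58.8% to 87.6%, so the extremes were mostly high. In a set A library the share was at most 0.324%. The lowest of these, 58.8%, is consistent with few original DNA molecules behind the reads of each site, and sites without a methylated read are unlisted, which would raise the mean. Fewer reads per site are argued against, since a set B library reached a median of 43 reads per listed site and set A at most 24. Diet or age are argued against too, since the set B controls of P90 lay at least 21.2 points above the set A controls of the same age and diet. Those means are over the sites of each library, which differ. At the same sites the set B controls lay 11.5 and 13.8 points above the set A mean. That mean covers both ages and diets, so the gap at the same sites cannot decide on either. Different processing of the sets by the authors stays open.

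Around CpG sites that differed by diet at P7, neighbours within 100 bp shifted by a median of 4.27% of the shift of the called site (bootstrap interval 1.09 to 8.56), with 66.3% of neighbourhoods in the same direction, against 65.6% and 96.1% around sites called for age. This argues against a change of similar size shared by neighbouring sites and leaves a small shared shift open. A sequence variant at the CpG, carried by animals of one diet group, is consistent with the 4.27%, as are single-site changes and chance, which is not excluded for sites (6 of 35 splits gave as many; real 109, highest other 172) or windows (12 of 35; real 3, highest other 15). At the chromosome 2 CpG, control P90 replicate 2 held 50.0% on both strands and replicate 1 held 95.5% and 97.1%, while on the minus strand high-fat P90 replicates 1 and 4 held 11.9% (109 reads) and 100% (91 reads). At the chromosome 13 site the set A controls of P90 held 91.7% and 91.9% and at the chromosome 18 site 97.8% and 97.3%, nearer to the high-fat P7 means (85.0% and 99.0%) than to the control P7 means (37.2% and 52.8%).

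Windows of low methylation were higher at P90 in set A controls, of which listing only sites with a methylated read would give 0.636% of the mean difference of 10.7 points in the 1009 windows called higher under 20%. Windows under 10% changed by a median of 2.64 points (79.2% of them above 0), over the 1 point set beforehand as what more unconverted cytosines would give. The 79 windows under 5% changed by 0.861 points (69.6% above 0), under that 1 point. The 2.64 points are 24.8% of the mean difference of 10.7 points. That share decides nothing on the whole cause, since the mean is over windows picked for being higher. All windows at 0 to 20% changed by a median of 3.93 points. Mitochondrial DNA argues against unconverted cytosines, though only sites with a methylated read enter. At listed sites both P90 libraries (0.276% and 0.285%) lay narrowly below all 4 P7 libraries (0.296% to 0.336%). The lowest P90 minus the highest P7 value, which is the largest gap, was -0.0591 points. Age, and a change in cell composition with it, stay open as untested. With 15 splits of 6 libraries a share under 0.05 cannot be reached (real 11259, highest other 0).

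Among 66 groups of 4 values, 5 held a value far from the others; in 4 of the 5 the others were at exactly 100%, where any unmethylated read stands out. Control P7 replicate 2 held 81.5% in the chromosome 4 window. High-fat P90 replicate 2 held 99.7% in the chromosome 5 window (also in the interaction), 99.5% at the chromosome 18 site and 99.87% in the chromosome 13 window.

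The diet difference differed between ages by 2.21 points on chromosome 13, 12.8 on chromosome X, 11.1 on chromosome 5 and 10.2 on chromosome 2. Of 100 splits of diet within age, 18 gave as many windows (real 4, highest other 9), and of 100 within age and library set, 45 did (highest other 12), so chance is not excluded. For diet at P90, 8 of 35 splits gave as many windows (real 1, highest other 5) and 2 of 35 as many sites (real 10, highest other 23), so chance is not excluded, but these splits exchanged libraries between the sets, whose spread differs. Within set B there are 15 splits, too few for a share under 0.05; 7 gave as many windows (real 1, highest other 5) and 2 as many sites (real 10, highest other 23). For age in all 8 controls 0 windows were called, so that all 35 splits had to give as many and nothing follows from them (highest other 0).

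Of the sites read at least 10 times in some set B library, 99.94% entered no P90 test. At listed mitochondrial sites the methylated share of reads was 1.21% to 6.35% in set B and 0.276% to 0.352% in set A.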

How the results depend on the processing

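The alternatives for set A alone, a minimum of 5 reads, a mean of at least 30%, named chromosomes and no robust step were chosen after the data were seen. Gene list and promoter alternatives were not run. The cause of the changes below was not tested, except where fewer features were tested. Named windows and sites were picked for the smallest p, and most alternatives test the same libraries again. That they keep passing therefore says little about the other calls. All 137 tests of the 10 windows named for age and all 64 of the 4 sites named for diet at P7 kept direction and side of the threshold; the 3 P7 windows did so in 36 of 49.

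Diet at P7, windows (3): Fisher 2179, 5 sites 1, mean of 30% 6, limma 0, leaving out libraries 3 to 15. Sites (109): no robust step 361, Fisher 767, 20 reads 71, no upper limit 167, strands merged 239, edgeR 222, limma 12, leaving out libraries 101 to 197. The 197 came without high-fat P7 replicate 1, and windows rose to 15 without it. The mean difference (-0.340 points) ranged from -0.724 to 0.232 when a library was left out and turned to 0.232 without high-fat replicate 3; it was -0.892 with reads summed.

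Diet at P90, windows (1): Fisher 59, 5 sites 0, mean of 30% 2, 5 reads 10, thinned 0, edgeR 0, limma 2, leaving out libraries 1 to 7. Sites (10): Fisher 447, 20 reads 4, strands merged 37, 5 reads 38, and 0 when thinned, in set B alone, without set term, in edgeR and in limma; leaving out libraries 0 to 44. Without control replicate 3, the site on chromosome 13 held 100% in control replicate 4 and in each high-fat library. No difference within set B was left there (adjusted p = 1, leaving out libraries 0.00525 to 1). The site on chromosome 18 reversed without control replicate 4 (adjusted p = 1, leaving out libraries 0.00538 to 1). The mean difference (1.62 points) was 4.76 with reads summed and 1.01 in set B alone, and ranged from 0.997 to 2.41 when a library was left out.

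Age, windows (0): set A alone 11259, leaving out libraries 0 to 425. In the 4 set A libraries with title numbers 3 and 4, 6222 windows were called without and 4644 with the replicate block; their differences correlated at -0.0371, which does not show whether the numbers mark a shared litter, so they were not used as pairs. In set A alone (11259): 20 reads 7333, 5 sites 7108, limma 5605, leaving out libraries 6179 to 10586. A mean of at least 30% gave 8418, of which 50.7% were higher, against 60.4% of all.

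Interaction, windows (4): 20 reads 0, no upper limit 1, 5 sites 2, 5 reads 22 (17 higher, 5 lower), edgeR 1 (lower), limma 2 (1 higher, 1 lower), leaving out libraries 1 to 12. The chromosome 20 window reversed without control P90 replicate 3 (adjusted p = 0.846; leaving out libraries 0.00494 to 0.846). The windows on chromosomes 13, 5, X and 2 did not pass in 3 of 24, 12 of 23, 17 of 24 and 19 of 24 alternatives.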

Other observations

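The values of the next paragraph were chosen only after the change with age in set A was seen, and the test of the last paragraph before its result was seen.

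The age change was also seen in single sites: of 637268 CpG sites in set A controls, 14665 were higher and 7377 lower at P90. Around sites called for age, 96.1% of the neighbourhoods moved the same way as the called site. Of the windows called higher, 1610 differed by at least 20 points and 199 by at least 30, and of those called lower, 752 and 99. Windows with 17 to 307 CpG listed in any library (strands merged) were called higher in 9.45% and lower in 5.14% of cases. Those with 1 to 7 were called in 6.09% and 3.80%. The count is of listed CpG, not of all CpG in the genome sequence, so it also depends on coverage. The median change of all windows was 0.607 points in the former and 0.584 in the latter, and that of windows called higher 12.6 and 17.2 points. The run on chromosome 5, 149365001 to 149369000 held 45.9% ± 3.15 (SD, n = 4) at P7 and 65.7% and 69.5% at P90.

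The hypothesis was that maternal high-fat diet shifts P7 methylation toward or away from the P90 state. Windows were called between the 2 P90 controls of set A and all 8 P7 libraries (7701 higher, 5061 lower). The mean over the first minus the second was -33.1 ± 1.54 points (SD, n = 4) in high-fat and -32.3 ± 0.756 (SD, n = 4) in control P7 libraries, and -4.15 and -4.58 in the P90 libraries. The exact permutation p was 0.343, two-sided, so a shift was not detected. A p of 0.05 or more had been set beforehand as arguing against a shift, but that bound was wrong, since a missed threshold with 4 libraries per group does not show that values are equal.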
